A study of Mus musculus with 4 samples.

How the data were processed

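CD45-positive cells were sorted from subcutaneous MC38 tumours (a mouse colon adenocarcinoma line) and read by droplet single-cell RNA sequencing. Per the labels, 100000 MC38 cells were injected into mice aged 8 weeks and tumours were taken on day 16, digested with collagenase, frozen and thawed before the sort. There were 4 libraries, 2 labelled WT and 2 labelled cKO for Ufl1, the ligase that attaches the ubiquitin-like modifier UFM1 to proteins. The series title places the ablation in T cells; the labels give neither the Cre driver nor the exons removed. They do not say whether each library came from a separate animal, so p-values for single genes and shares measure only the spread between these libraries.

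The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger. The file headers name version 6.1.1, and the submitters' notes also name CASAVA 1.8 and Seurat. The genome build and annotation were not given in the sources used here, and 31107 of the 31253 feature identifiers are in GENCODE M21. The 48 symbols carried by more than 1 feature were kept as separate features. The labels name a kit that reads the end of the transcript with the poly(A) tail. In 4700 T-like cells, however, V and J segments carried 50314 of the receptor UMIs and constant segments 14373, so that V and J made up 77.8%. No barcode began with AAACCC. The V and J share was 75.6% to 78.5% in single libraries. Constant segments lie nearer the poly(A) tail, so these values argue against the end that the labels name.

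The files held 32801 barcodes, with 64141857 to 79747752 UMIs per library. Cells with at least 300 genes and at most 15% mitochondrial UMIs were kept, which removed 405 barcodes. Scrublet's automatic threshold called 13 doublets, or 0.025% to 0.083% of a library, and was judged not to have worked. After that was seen, the cells with the highest doublet scores were removed at a rate of 0.8% per 1000 cells, 2117 in all, which left 30279 cells. Counts were normalised to 10000 per cell and log-transformed. Then 2000 variable genes (receptor segments, mitochondrial, ribosomal and sex-linked genes and Ufl1 left out), 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 gave 30 clusters. The 9660 cells of the T and NK clusters were clustered again into 19. Libraries were not integrated. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and pandas 2.3.3.

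Cell annotations were not used, and clusters were named from 140 marker genes, 1 of which was not among the features. The name "T-like" and its kind mean a cluster named in this way. The markers were fixed before the data were examined. The naming rules were set in 3 passes after cluster markers and cell numbers were seen and before any test between genotypes. A T-like cluster needed at least 400 CPM of Cd3e plus Cd3d, a Treg-like cluster also 100 CPM of Foxp3, and a gamma-delta T-like cluster 200 CPM of Trdc. CD8 and CD4 clusters needed the co-receptor's UMIs in at least 30% of cells and at 4 times the share of the other, and every named cluster a marker score of at least 0.35. Clusters whose leading gene or most of whose leading genes belong to another cell type were kept out of the named classes, also the NK cluster whose further leading genes are interferon-induced. In WT replicates 1 and 2 and cKO replicates 1 and 2, these were macrophage clusters with other RNA (2.34%, 6.57%, 5.78% and 2.74% of cells), NK clusters with other RNA (1.81%, 1.06%, 2.28% and 2.06%) and T clusters with myeloid RNA (1.11%, 0.878%, 1.77% and 2.36%). Unnamed clusters held 2.91%, 0.612%, 1.56% and 4.69%. T-like clusters stayed unresolved where they met no subset's rule or where their 10 leading genes held more markers of another class than of their own. They count among all T-like cells and made up 4.57%, 6.36%, 4.49% and 6.50% of cells, more than any T subset. A cluster led by cell cycle genes such as Top2a and Rrm2 is among them. The subsets may therefore lack part of their cells.

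Raw UMI counts were summed per library and class, for each class with at least 20 cells in every library. Sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), cKO against WT. DESeq2 1.42.0 gave a Wald test beside it. Differences of effect between classes were tested as an interaction with the library as a block. Values in CPM are normalised by TMM, except where raw CPM is named. Errors of log2 fold changes are standard errors. Shares of cells and the log2 ratio of CD8 T-like to Treg-like cells were compared by an exact two-sided permutation test of 2 against 2 libraries, whose smallest p is 0.333, so it cannot reach 0.05. Cell numbers were also fitted with edgeR. Poisson intervals of levels cover 95% and counting error only. With 2 against 2 libraries, chance sets the groups apart for 33.3% of genes.

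The named genes follow a rule fixed before the data were examined. Ufl1 and Pdcd1 are given in every T class. Per main class (all T-like, CD8, CD4, Treg) up to 10 higher and 10 lower genes with the largest change are named among those with an adjusted p under 0.05, a mean CPM of at least 10 and groups apart, and up to 5 of each in further classes. Where fewer than 5 genes pass, the 5 with the smallest p are given as values. Receptor and immunoglobulin segments, mitochondrial and ribosomal genes, Xist, Tsix and Y-linked genes, unnamed gene models, and genes with over 10 times the CPM in another class (carried-over RNA) are left out of the ranking and given as counts. From each list, members that passed are named, up to 4, or where none passed the 2 with the smallest p.

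Also fixed were 342 genes in 22 lists, 3 of them not among the features. The lists are the UFMylation pathway, ER stress and the unfolded protein response, cytotoxic effectors, inhibitory receptors and exhaustion, naive and memory T cells, T cell receptor activation, Treg suppressive genes, the type I interferon response, the interferon gamma response, MHC class II presentation, proliferation, inflammatory macrophages, alternatively activated macrophages, chemokines for lymphocytes, hypoxia and glycolysis, oxidative phosphorylation, apoptosis and p53, dissociation and heat shock, and markers of other cells (myeloid, tumour and stroma, erythroid and platelet, B lineage). Lists with at least 5 tested members in a class were tested with camera in limma 3.58.1 with an inter-gene correlation preset to 0.01, adjusted over all 243 pairs of list and class. With the preset value, camera's p-values rest mainly on the spread over genes and hardly on that between libraries. Camera with an estimated correlation and fry stood beside it. Both rest on 2 residual degrees of freedom per class, which leaves them little power after adjustment over 243 pairs. A list that they do not call is therefore not shown to be unchanged. The tumour and stroma list had fewer than 5 tested members in every class and was not tested.

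The tests were checked on simulated data, made from the same sums with known changes added. In all T-like cells, edgeR recovered 22.4% of 67 genes changed 1.5-fold, 79.1% of those changed 2-fold and 100% of 66 changed 4-fold, and it called 13 of 10932 unchanged genes. In CD8 T-like cells it recovered 4.48%, 29.9% and 98.5%, and in macrophage-like cells 41.8%, 94.0% and 100%. For the difference between CD8 T-like and Treg-like cells it recovered 1.49%, 10.4% and 89.4%. When a list was raised 1.5-fold in all T-like cells, camera called it (adjusted p = 2.7e-28 for type I interferon and 2.72e-44 for oxidative phosphorylation), with 0 and 1 of 19 other lists called. The simulated genes were drawn independently of each other. The check therefore cannot show how often camera with the preset correlation calls lists whose genes vary together.

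The alternatives tried were DESeq2 size factors, the Wald test, no expression filter, the replicate number as a block, each library left out, doublet calls kept, cells with at least 800 genes and at most 8% mitochondrial UMIs, resolution 2, and gates on Cd4, Cd8a and Cd8b1 UMIs. Chosen after seeing the data were the return of the macrophage-like and of the NK-like cells kept out for other RNA, the alternatives for the further classes, the gate for single genes and the left-out libraries for gene lists. With a library left out, the lone library of its group is assumed to vary like the other group. Mast cell-like and neutrophil-like cells were too few to test.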

Results

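Immune cells of MC38 tumours were profiled on day 16 after injection to ask how loss of Ufl1, which the series title places in T cells, affects tumour-infiltrating immune cells and the PD-1 receptor. WT replicates 1 and 2 held 7352 and 9466 barcodes with 64141857 and 77030913 UMIs, and cKO replicates 1 and 2 held 7885 and 8098 barcodes with 71702863 and 79747752 UMIs. After filtering, 6845, 8657, 7290 and 7487 cells remained, at median depths of 7159, 7011, 7166 and 8165 UMIs. Every comparison sets 2 libraries labelled cKO against 2 labelled WT, and values for single libraries are given in the order WT replicate 1, WT replicate 2, cKO replicate 1, cKO replicate 2. cKO replicate 2 stood apart in its sex-linked transcripts: Xist, the RNA that silences an X chromosome in female cells, was at 292 CPM there against 0.165, 0.252 and 0.138 CPM in the other libraries, and the Y-linked Ddx3y had 1 UMI against 2759, 3312 and 2726. The 2 cKO libraries therefore differ from each other in a property that the labels do not give.

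Ufl1 encodes the ligase of the UFM1 conjugation system (chromosome 4, 25248600 to 25281821, minus strand, in GENCODE M21). In all T-like cells its raw level was 16.4 CPM (95% Poisson interval 13.2 to 20.2) and 16.6 CPM (14.4 to 19.0) in the WT libraries, and 13.9 CPM (11.2 to 17.1) and 20.1 CPM (17.5 to 23.0) in the cKO libraries, from 88, 205, 91 and 218 UMIs. The log2 fold change was −0.00028 ± 0.22 in edgeR (adjusted p = 1.00, 95% interval of the fold 0.699 to 1.43). Raw levels in CD8 T-like cells were 15.6, 19.7, 19.0 and 19.2 CPM from 14, 89, 25 and 73 UMIs, with a log2 fold change of −0.0052 ± 0.26, whose sign turned with DESeq2 (0.025), with doublets kept (0.049), at resolution 2 (2.2e-05) and without WT replicate 2 (0.26) or cKO replicate 2 (0.036). The fold changes were 0.38 ± 0.38 in conventional CD4 T-like, 0.32 ± 0.44 in Treg-like and 0.33 ± 0.47 in gamma-delta T-like cells. Without cKO replicate 2 they were −0.091 in Treg-like and −0.098 in gamma-delta T-like cells, and without WT replicate 2 −0.12 in gamma-delta T-like cells. The labels do not say which exons were removed and the counts pool the whole gene, so this level checks nothing about the ablation. The sign in all T-like cells turned with single libraries, at −0.059 and 0.062 without WT replicates 1 and 2 and at 0.22 and −0.30 without cKO replicates 1 and 2.

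Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553, minus strand), did not pass the threshold in any T-like class. In CD8 T-like cells its raw level was 342 and 886 CPM in the WT libraries and 581 and 690 CPM in the cKO libraries, a log2 fold change of −0.032 ± 0.41 (adjusted p = 1.00, 95% interval of the fold 0.498 to 1.92). In all T-like cells it was 169, 449, 253 and 409 CPM, a log2 fold change of 0.018 ± 0.44. In conventional CD4 T-like cells its level normalised by TMM was 114 and 160.0 CPM in the WT and 113 and 98.6 CPM in the cKO libraries. The groups thus lay apart (−0.39 ± 0.20 in edgeR, adjusted p = 1.00, and −0.11 without WT replicate 2). The fold changes were 0.27 ± 0.27 in Treg-like and 0.20 ± 0.24 in gamma-delta T-like cells. Signs turned without WT replicate 1 in all T-like (−0.55) and Treg-like cells (−0.034), and without cKO replicate 2 in all T-like (−0.37), Treg-like (−0.14) and gamma-delta T-like cells (−0.17). Transcript counts carry no information on UFMylation or on the amount of PD-1 protein. The CD8 value moved to −0.56 without WT replicate 1, 0.86 without WT replicate 2, 0.054 without cKO replicate 1 and −0.12 without cKO replicate 2. A cluster with Pdcd1 among its leading genes held 15, 328, 48 and 203 of the 146, 489, 130 and 437 CD8 T-like cells. Its share ordered the libraries as the Pdcd1 level did. Pdcd1 helps define this cluster, so its share is no separate measure.

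**Figure D1:**
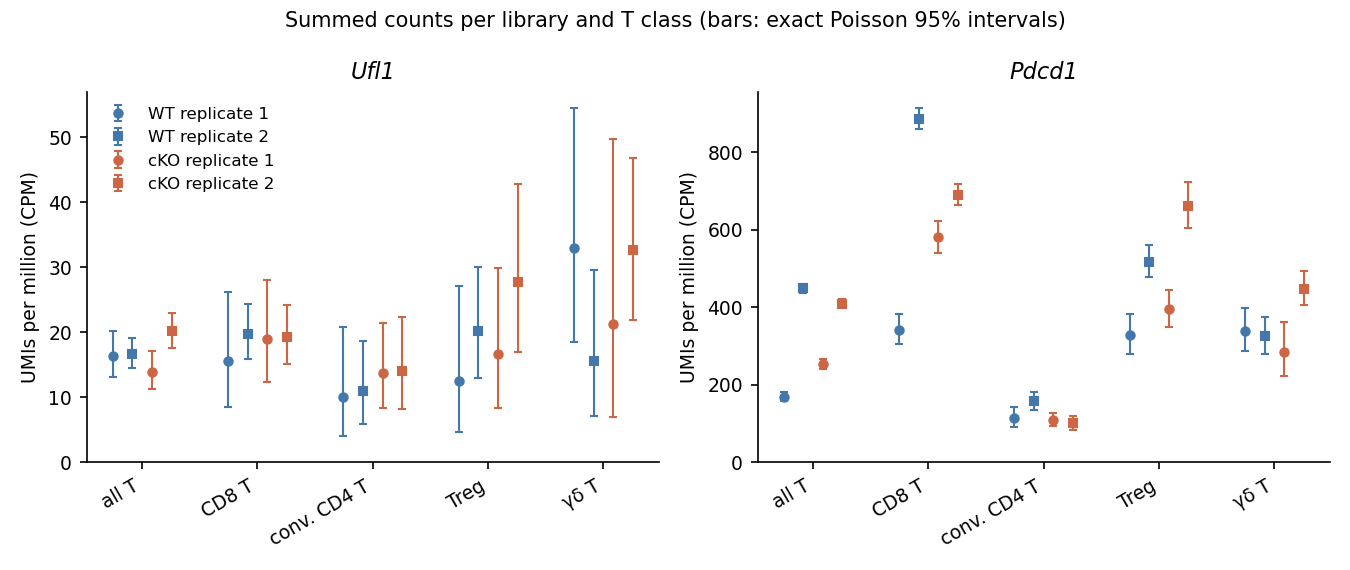
Raw level of Ufl1 and Pdcd1 (CPM) in each library and T-like class, with points for WT and cKO libraries and bars for 95% Poisson intervals, which cover counting error only. Ufl1 in all T-like cells spans 13.9 to 20.1 CPM in the cKO libraries around the WT values of 16.4 and 16.6 CPM.

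The makeup of the infiltrate was compared to ask whether the ablation changed the number of T cells in the tumour. All T-like cells made up 15.2% ± 5.72 of WT cells and 15.3% ± 5.04 of cKO cells (SD, n = 2 each; 11.2%, 19.3%, 11.7% and 18.9%; exact permutation p = 1.00). CD8 T-like cells, the killer subset, made up 3.89% ± 2.49 and 3.81% ± 2.87 (2.13%, 5.65%, 1.78% and 5.84%), and Treg-like cells, the suppressive subset marked by Foxp3, 2.11% ± 1.45 and 1.61% ± 0.0112. Conventional CD4 T-like cells made up 2.37% ± 0.603 and 3.00% ± 0.181 (1.94%, 2.80%, 3.13% and 2.87%), and the groups lay apart, with an exact permutation p of 0.333 and a log2 fold change of 0.34 ± 0.71 in edgeR (adjusted p = 0.992). The ratio of CD8 T-like to Treg-like cells was 1.97, 1.8, 1.10 and 3.64. B-like cells were at 2.45% and 1.99% in the WT and 3.48% and 4.54% in the cKO libraries, outside the spread within either group, but the exact permutation p of 0.333 is the smallest that this design can give, and edgeR on cell numbers gave a log2 fold change of 0.85 ± 0.71 (adjusted p = 0.992). cDC2-like cells were at 10.7%, 7.73%, 6.50% and 7.69%, where the groups lay apart by 7.73% against 7.69% (exact permutation p = 0.333). With the stricter cell filter they overlapped, at 7.94% in WT replicate 2 and 8.39% in cKO replicate 2. Macrophage-like cells ranged from 13.4% to 22.7% in the WT and from 11.8% to 20.6% in the cKO libraries, monocyte-like cells made up 28.6% ± 1.55 and 29.4% ± 6.03, and NK-like cells 13.6% ± 10.9 and 11.8% ± 5.91. Among the clusters kept out, the groups also lay apart for T clusters with myeloid RNA (1.11%, 0.878%, 1.77% and 2.36%) and NK clusters with other RNA (1.81%, 1.06%, 2.28% and 2.06%). Each had an exact permutation p of 0.333, and edgeR gave log2 fold changes of 1.06 ± 0.72 and 0.59 ± 0.71 (adjusted p = 0.992 for both). The CD45 sort sets the denominator, so shares say nothing of numbers per tumour. Single libraries decide the sign of the differences in CD8 and all T-like cells: the CD8 difference of −0.081 percentage points became −1.84, 1.68, 1.95 and −2.11, and that of all T-like cells of 0.072 became −3.97, 4.12, 3.64 and −3.49, without WT replicates 1 and 2 and cKO replicates 1 and 2 in turn.

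**Figure D2:**
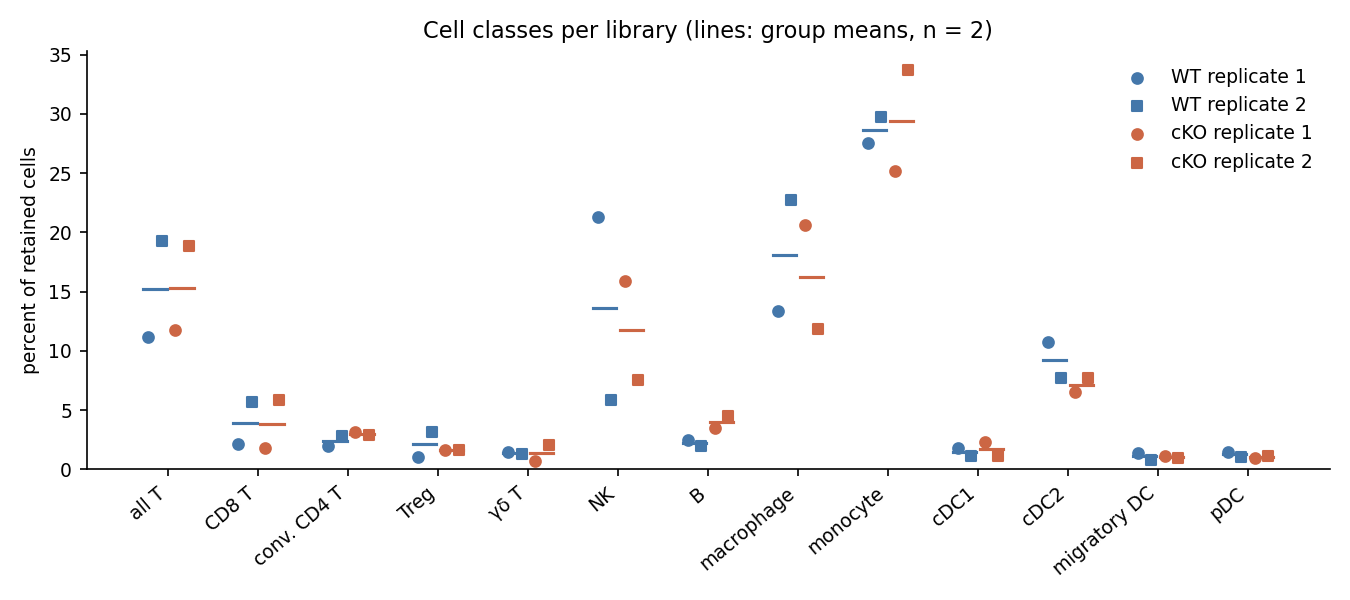
Share of kept cells (%) in each class and library, with points for the WT and cKO libraries and lines for group means (n = 2). CD8 T-like cells lie at 2.13% and 5.65% in the WT and at 1.78% and 5.84% in the cKO libraries.

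In all T-like cells no gene passed the threshold, while genes of the type I interferon response lay higher in the cKO libraries as a group. All 21 tested members had positive log2 fold changes, with a median of 0.32, among them Oasl2 and Oas3, antiviral members of the oligoadenylate synthetase family, at 0.50 ± 0.13 and 0.53 ± 0.16. Camera called the list (adjusted p = 1.75e-11, and adjusted p = 0.824 with an estimated correlation). The interferon gamma response list was called with 15 of 21 genes higher (median 0.10, adjusted p = 0.0495, and adjusted p = 0.824 with an estimated correlation), led by the immunity-related GTPase Iigp1 at 0.46 ± 0.14. The dissociation and heat shock list was called with 17 of 20 higher (median 0.093, adjusted p = 0.00114, and 0.824 as adjusted p with an estimated correlation), with the chaperone genes Hspa1b at 0.55 ± 0.16 and Hsph1 at 0.43 ± 0.12. Lists called lower were Treg suppressive genes (15 of 17 lower, median −0.19, adjusted p = 0.0117, with Foxp3 at −0.37 ± 0.21), oxidative phosphorylation (21 of 26 lower, median −0.11, adjusted p = 0.00715, with Ndufa4 at −0.30 ± 0.11) and proliferation (17 of 22 lower, median −0.11, adjusted p = 0.0191, with the thymidylate synthase gene Tyms at −0.26 ± 0.13). With an estimated correlation their adjusted p was 0.824, 0.891 and 0.888. The Treg suppressive list was not called within Treg-like cells (12 of 17 lower, median −0.073, adjusted p = 0.329), which were 74, 271, 118 and 120 of 765, 1668, 855 and 1412 T-like cells.

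Among single genes of all T-like cells, those with the smallest p were Gadd45g, a stress-induced gene, at 0.52 ± 0.13, Sema6d at 1.03 ± 0.25, Ifng, the gene for interferon gamma, at 0.51 ± 0.13, AI467606 at 0.49 ± 0.13 and Oasl2. Their adjusted p was 1.00. Of 11132 genes tested, edgeR called 0, 206 had an unadjusted p under 0.05 (557 expected by chance), and DESeq2 called 0. The groups did not overlap in 28.7% of genes against 33.3% by chance. The UFMylation pathway list had 2 members higher and 6 lower (median −0.060, adjusted p = 0.291), with Ufc1, the UFM1-conjugating enzyme gene, at −0.21 ± 0.11. Also not called were cytotoxic effectors (13 of 18 lower, adjusted p = 0.284), inhibitory receptors and exhaustion (9 of 17 lower, adjusted p = 0.628) with Cd160 at −0.43 ± 0.12, T cell receptor activation (adjusted p = 0.805), ER stress (adjusted p = 0.626) and the B lineage markers (5 of 5 higher, adjusted p = 0.142). Adjusted over the list alone, no member of any of these lists passed.

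Single libraries changed these results. Without WT replicate 1, WT replicate 2 or cKO replicate 1, edgeR called 15, 70 and 6 genes. Without WT replicate 1 the adjusted p was 0.168 for type I interferon, 0.742 for interferon gamma, 0.161 for heat shock and 0.598 for proliferation, which turned upward. Without WT replicate 2 it was 0.881 for Treg suppressive genes and 0.263 for oxidative phosphorylation, which turned upward. Without cKO replicate 1 it was 0.196 for proliferation and 0.0641 for oxidative phosphorylation. Without cKO replicate 2 it was 0.0719 for type I interferon, 0.583 for interferon gamma, 0.209 for heat shock, 0.85 for Treg suppressive genes and 0.121 for oxidative phosphorylation.

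CD8 T-like cells were drawn from a cluster led by Gzmk (131, 161, 82 and 234 cells) and one led by Pdcd1 and Lag3 (15, 328, 48 and 203 cells). Their mix varied between libraries, and the first also had the haemoglobin gene Hbb-bs and the interferon-induced Ifit3 among its leading genes. In this class the MHC class II presentation list lay higher in the cKO libraries, with 6 of 8 members higher and a median of 0.49 (adjusted p = 0.00023, and adjusted p = 0.824 with an estimated correlation). Cd74, the invariant chain that escorts class II molecules, was at 107, 97.9, 249 and 203 CPM (1.14 ± 0.19), the member that passed when adjusted over the list alone, and H2-Ab1 was at 1.18 ± 0.44. Cd74 and H2-Ab1 were also leading genes of a T cluster kept out for myeloid RNA (1, 4, 5 and 59 cells). Whether the rise is RNA carried over from antigen-presenting cells or expression by CD8 T cells was not tested. The myeloid list, which also holds Cd74, was not called in this class (3 of 11 higher, median −0.12, adjusted p = 0.641). It was called higher without WT replicate 1 (0.0054) or cKO replicate 2 (0.0229) and lower without WT replicate 2 (0.0189). Also called higher were proliferation (17 of 22, median 0.13, adjusted p = 0.0175) with Top2a at 0.52 ± 0.25 (−0.44 at resolution 2 and −0.17 with the UMI gate), hypoxia and glycolysis (17 of 21, median 0.11, adjusted p = 0.0161) with the glucose transporter gene Slc2a3 at 0.68 ± 0.21, and type I interferon (17 of 20, median 0.16, adjusted p = 0.0223) with Oasl2 at 0.88 ± 0.31. With an estimated correlation their adjusted p was 0.824, 0.888 and 0.891. The T-like cluster led by cell cycle genes stayed unresolved and lies outside this class, so the proliferation call leaves out its cells.

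Inhibitory receptors and exhaustion were not called in CD8 T-like cells (12 of 16 lower, median −0.15, adjusted p = 0.201), with Cd160 at −0.34 ± 0.23 and Tigit at −0.27 ± 0.18. Nor were cytotoxic effectors (11 of 18 lower, median −0.093, adjusted p = 0.67), with the death ligand gene Fasl at −0.38 ± 0.17, or the naive and memory list (9 of 14 lower, adjusted p = 0.359). The UFMylation list had 4 members higher and 4 lower, with a median of 0.011 but a mean of −0.067, and its test pointed down (adjusted p = 0.547). The genes with the smallest p were Hspa1a (0.88 ± 0.23) and Hspa1b (0.73 ± 0.21), both inducible heat shock proteins, Sema6d (1.13 ± 0.31), Slc16a11 (1.08 ± 0.31) and B4galt7 (0.90 ± 0.28), all with an adjusted p of 1.00. Of 9248 genes edgeR called 0, 117 had an unadjusted p under 0.05 (462 expected by chance), and DESeq2 called 1. The groups did not overlap in 25.6% against 33.3% by chance. Without cKO replicate 1 edgeR called 6 genes, and without WT replicate 1 or cKO replicate 2 it called 1. Adjusted p rose above the threshold for MHC class II without WT replicate 2 (0.228) or cKO replicate 1 (0.26), for proliferation without WT replicate 1 (0.325) or cKO replicate 2 (0.314), and for glycolysis without WT replicate 1 (0.122, downward) or cKO replicate 1 (0.685). Type I interferon turned downward without WT replicate 2 (0.369) or cKO replicate 2 (0.237).

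In conventional CD4 T-like cells the gene that passed was the receptor segment Trav7d-3 (2.89, 1.71, 35.9 and 41.2 CPM; log2 fold change 4.09 ± 0.44, adjusted p = 0.0288), which lies outside the rule for named genes and was named after its values were seen. Type I interferon genes lay higher as a list (18 of 20, median 0.14, adjusted p = 0.00038, and adjusted p = 0.888 with an estimated correlation), with Oas1a at 0.50 ± 0.24. T cell receptor activation genes lay lower (14 of 20, median −0.074, adjusted p = 0.0414, and adjusted p = 0.824 with an estimated correlation), with Myc at −0.43 ± 0.24 (0.39 with the UMI gate) and the co-stimulatory receptor gene Tnfrsf9 at −0.37 ± 0.21. Macrophage transcripts were higher in the same libraries: the myeloid list had 10 of 10 members higher (median 0.28, adjusted p = 0.00141, and adjusted p = 0.824 with an estimated correlation), with Apoe at 0.73 ± 0.28.

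The genes with the smallest p after Trav7d-3 in conventional CD4 T-like cells were Mpp7 (−1.25 ± 0.24), Lztr1 (1.27 ± 0.33), Ap2b1 (0.93 ± 0.25), Paip1 (−1.14 ± 0.31) and Trim44 (1.09 ± 0.31), all with an adjusted p of 1.00. The cytotoxic and chemokine genes Xcl1 (−1.26 ± 0.38, but 0.80 with the UMI gate) and Cxcl2 (−2.19 ± 0.45) and the checkpoint gene Ctla4 (−0.34 ± 0.14) were lower without passing over all genes. Cxcl2 passed when adjusted over the 6 tested inflammatory macrophage genes alone (adjusted p = 0.00408). Of 7882 genes, 1 passed in edgeR, 214 had an unadjusted p under 0.05 (394 expected by chance), and DESeq2 called 3. The groups did not overlap in 30.4% against 33.3% by chance. Without WT replicates 1 and 2 edgeR called 2 and 35 genes, and without cKO replicates 1 and 2 it called 9 and 4. T cell receptor activation lost its call without any of the libraries (adjusted p 0.1 and 0.211 without WT replicates 1 and 2, 0.0933 and 0.25 without cKO replicates 1 and 2). Type I interferon turned downward without WT replicate 1 (8.63e-07), and the myeloid list lost its call without cKO replicate 1 (0.722).

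In Treg-like cells 2 receptor segments passed and were named after their values were seen, Trbv20 (18.8, 14.3, 117 and 84.4 CPM; 2.66 ± 0.32, adjusted p = 0.00649) and Trav14n-3 (10.4, 13.4, 69.5 and 71.7 CPM; 2.50 ± 0.33, adjusted p = 0.0084). Gadd45g was at 1.35 ± 0.28 (adjusted p = 0.378) and Il1r2, the decoy receptor for interleukin 1, at −1.36 ± 0.31 (adjusted p = 0.67). The integrin gene Itga4 was at 0.86 ± 0.22, Hopx at −0.73 ± 0.19 and Hspa1b at 0.71 ± 0.18. The heat shock list lay higher (15 of 20, median 0.20, adjusted p = 6.27e-05, with 2 genes passing when adjusted over the list alone), as did type I interferon (17 of 20, median 0.26, adjusted p = 7.18e-05) with Oas1a at 0.67 ± 0.24. With an estimated correlation their adjusted p was 0.824 and 0.883. The myeloid markers were higher too (9 of 11, median 0.33, adjusted p = 0.0048, and adjusted p = 0.824 with an estimated correlation), with C1qc at 0.91 ± 0.33. Tnfrsf4, a Treg activation marker, was at −0.48 ± 0.19, and Prf1, the perforin gene, at 1.48 ± 0.47. Of 7177 genes 2 passed in edgeR, 233 had an unadjusted p under 0.05 (359 expected by chance) and DESeq2 called 2. Left-out libraries gave 4 and 9 genes (WT replicates 1 and 2) and 16 and 5 (cKO replicates 1 and 2). Adjusted p rose to 0.12 for heat shock and 0.451 for type I interferon, downward, without WT replicate 1. It was 0.427 for type I interferon without cKO replicate 2, and 0.426 and 0.099 for the myeloid list without WT replicate 2 and cKO replicate 1.

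Gamma-delta T-like cells, an interleukin 17-producing population led by Il17a and Cd163l1, had lower levels of proliferation genes in the cKO libraries. Of 13 tested members 12 were lower, with a median of −0.31 (adjusted p = 8.73e-06, and adjusted p = 0.824 with an estimated correlation), and the call held with each library left out. Mki67, a marker of cycling cells, was at 175, 32.8, 22.7 and 20.8 CPM (−2.24 ± 0.67, adjusted p = 1.00), so WT replicate 1 stood far above the others, and Top2a was at −1.60 ± 0.56. The heat shock list lay higher (15 of 20, median 0.24, adjusted p = 0.00127, and adjusted p = 0.824 with an estimated correlation), though its adjusted p was 0.618 without cKO replicate 1. Type I interferon genes did too (14 of 17, median 0.24, adjusted p = 0.0247, and adjusted p = 0.891 with an estimated correlation), but they were called lower without WT replicate 1 (0.0452) and lost the call without cKO replicate 2 (0.245, downward). The alternatively activated macrophage list was higher in 4 of 5 (median 0.48, adjusted p = 0.0319, and adjusted p = 0.824 with an estimated correlation). Without WT replicate 2, cKO replicate 1 and cKO replicate 2 its adjusted p was 0.669, 0.0927 and 0.97, the first and last downward. The other genes with the smallest p were Hspa1a (0.90 ± 0.23), Tnfsf11 (−1.41 ± 0.38), Slc25a51 (1.88 ± 0.54) and Smyd2 (−1.11 ± 0.33). Of 5880 genes edgeR called 0, 120 had an unadjusted p under 0.05 (294 expected by chance) and DESeq2 called 0. The class held 99, 115, 52 and 153 cells.

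In NK-like cells, cytotoxic lymphocytes without a T cell receptor, type I interferon genes lay higher in the cKO libraries (18 of 19, median 0.40, adjusted p = 1.14e-09, and adjusted p = 0.824 with an estimated correlation), with Xaf1 at 0.47 ± 0.15 and Rtp4 at 0.47 ± 0.15. Ifng was at 158, 157, 248 and 257 CPM (0.68 ± 0.12, adjusted p = 1.00), and it passed when adjusted over the cytotoxic effector list alone. Hspa1a (0.72 ± 0.15), Gadd45g (0.73 ± 0.16), Hspa1b (0.65 ± 0.16) and Emb (−0.54 ± 0.13) followed. The heat shock list lay higher (15 of 20, median 0.053, adjusted p = 0.00715, and adjusted p = 0.824 with an estimated correlation). Its adjusted p was 0.574 and 0.389 without WT replicate 1 and cKO replicate 2. An NK cluster kept out of this class was led by the haemoglobin gene Hbb-bs but also by the interferon-induced Oasl1, Ifi44 and Rsad2. With it returned, as chosen after seeing the data, type I interferon genes were higher in 21 of 21 (median 0.48, adjusted p = 7.4e-16). The interferon gamma list (14 of 20, median 0.095, adjusted p = 0.0195) and, downward, proliferation (8 of 22 higher, median −0.19, adjusted p = 0.00884) were called as well. With this cluster returned, only camera with the preset correlation was run. Hypoxia and glycolysis genes lay lower (18 of 21, median −0.18, adjusted p = 0.00111) with Pgam1 at −0.37 ± 0.15, as did oxidative phosphorylation (21 of 26, median −0.097, adjusted p = 0.0132) with Ndufa4 at −0.28 ± 0.14. With an estimated correlation their adjusted p was 0.824 and 0.891. Of 10523 genes edgeR called 0, 329 had an unadjusted p under 0.05 (526 expected by chance) and DESeq2 called 2. Without WT replicates 1 and 2 edgeR called 11 genes and 1, and without cKO replicates 1 and 2 it called 27 and 19. Adjusted p was 0.209 for type I interferon without WT replicate 1, 0.512 and 0.431 for glycolysis without WT replicate 2 and cKO replicate 1, and 0.228 (upward) and 0.771 for oxidative phosphorylation without WT replicate 2 and cKO replicate 2.

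Macrophage-like cells were compared because the ablation is placed in T cells. Lymphocyte transcripts were higher in this class in the cKO libraries. Cytotoxic effectors lay higher in 14 of 18 (median 0.99, adjusted p = 6.86e-17, 7 genes passing when adjusted over the list alone), T cell receptor activation in 11 of 19 (median 0.51, adjusted p = 3.94e-16, 8 genes), Treg suppressive genes in 14 of 16 (median 0.63, adjusted p = 5.69e-10, 5 genes) and naive and memory genes in 10 of 14 (median 0.49, adjusted p = 2.12e-06, 3 genes). These calls held with each library left out, and with an estimated correlation their adjusted p was 0.824. Lat, an adaptor of T cell receptor signalling, was at 3.36, 4.20, 17.8 and 27.6 CPM (2.54 ± 0.26, adjusted p = 0.0733), Ifng at 1.82, 2.03, 8.44 and 19.8 CPM (2.82 ± 0.43, adjusted p = 0.139), Cd28 at 1.93 ± 0.28 and Tcf7 at 2.14 ± 0.43. Their levels were far below those of T-like cells. In addition, 56 transcripts carried over from other classes, mostly T and NK cell genes but also Igkc of B cells, averaged 1.5, 1.5, 3.65 and 7.60 UMIs per macrophage-like cell. CD8 T-like cells held 176 to 248 per cell. The 56 were picked for a larger change in macrophage-like than in T-like cells of these libraries, so their rise follows from that choice.

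Among genes that macrophages make, Gpnmb, a lysosomal glycoprotein gene, was at 0.80 ± 0.15 (adjusted p = 0.178), the haptoglobin gene Hp at 0.54 ± 0.11 (adjusted p = 0.274), the urokinase receptor gene Plaur at −0.55 ± 0.11 (adjusted p = 0.266), Grasp at −0.74 ± 0.12 (adjusted p = 0.157) and Mpp7 at −0.65 ± 0.14 (adjusted p = 0.297). With doublets kept Hp was at −0.13 and Mpp7 at 0.11. The inflammatory macrophage list lay lower (12 of 14, median −0.19, adjusted p = 0.000454, and adjusted p = 0.824 with an estimated correlation), with the neutrophil chemokine gene Cxcl1 at 52.3, 9.98, 2.91 and 3.05 CPM (−3.32 ± 0.74). The adjusted p of the list was 0.46 without WT replicate 1. The lymphocyte chemokine list lay higher (4 of 5, median 0.23, adjusted p = 0.0283, and adjusted p = 0.824 with an estimated correlation), with Ccl5 at 0.78 ± 0.13. Its adjusted p was 0.206 without WT replicate 2 and 0.967, downward, without cKO replicate 1. The alternatively activated list was called higher (12 of 16, median 0.11, adjusted p = 0.0418, and adjusted p = 0.843 with an estimated correlation), with adjusted p of 0.916 without WT replicate 2 and 0.582, downward, without cKO replicate 1. Inhibitory receptors and exhaustion were called at adjusted p = 0.0497 (9 of 15 higher, median 0.046, and adjusted p = 0.824 with an estimated correlation) with Tigit, a carried-over transcript, at 0.91 ± 0.29 (−0.29 with doublets kept). They lost the call without any of the libraries (0.06 and 0.0899 without WT replicates 1 and 2, 0.0521 and 0.067 without cKO replicates 1 and 2). Of 10807 genes edgeR called 0, 433 had an unadjusted p under 0.05 (540 expected by chance), and DESeq2 called 29 (27 higher, 2 lower). The groups did not overlap in 29.8% against 33.3% by chance. Without WT replicate 2 edgeR called 2 genes, and without cKO replicates 1 and 2 it called 132 and 60.

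**Figure D3:**
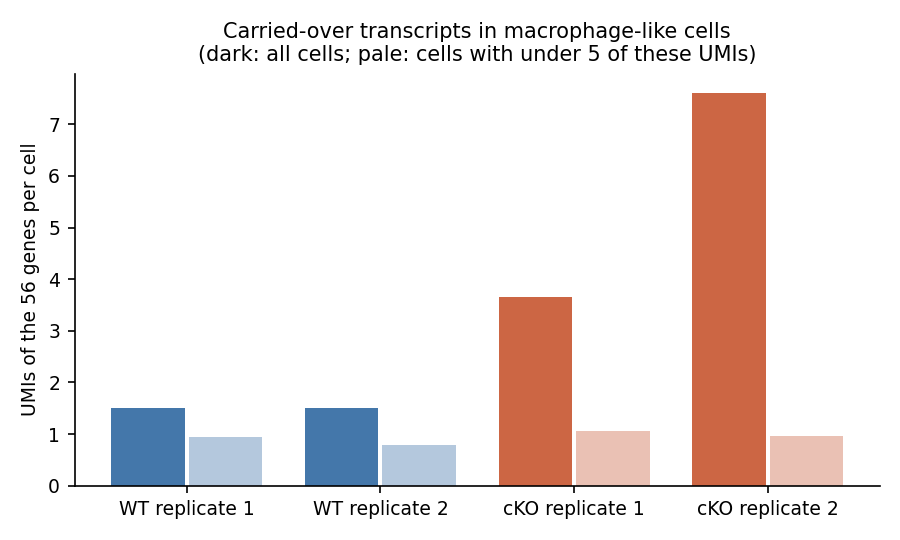
UMIs of 56 carried-over transcripts, mostly of T and NK cells, per macrophage-like cell in each library, for all cells and without the cells that hold 5 or more of them. The 56 were picked for a larger change in macrophage-like than in T-like cells of these libraries, so their rise follows from that choice. The values for all cells are 1.5 and 1.5 in the WT and 3.65 and 7.60 in the cKO libraries, and without those cells 0.937, 0.788, 1.05 and 0.960.

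In monocyte-like cells, genes induced by interferon gamma were higher in the cKO libraries as a group. All 21 tested members of that list had positive log2 fold changes (median 0.42, adjusted p = 3.39e-20, and adjusted p = 0.824 with an estimated correlation), 12 with the groups apart, and 8 passed when adjusted over the list alone. Iigp1 was at 13.3, 12.5, 39.9 and 43.9 CPM (1.70 ± 0.12, adjusted p = 0.052), and the guanylate-binding protein gene Gbp4 was at 0.70 ± 0.12. Tgtp1, a further interferon-inducible GTPase (1.27 ± 0.13, adjusted p = 0.205), the complement factor gene Cfb (0.93 ± 0.11, adjusted p = 0.258), Il18bp, an antagonist of interleukin 18 (0.82 ± 0.11, adjusted p = 0.266), and Gbp6 (1.04 ± 0.17, adjusted p = 0.562) followed. Type I interferon genes were also higher in 21 of 21 (median 0.45, adjusted p = 1.55e-17, and adjusted p = 0.824 with an estimated correlation), with Ifi44 at 1.51 ± 0.39. Both calls held with each library left out. The class of 1884, 2572, 1833 and 2521 cells includes a cluster led by the interferon-induced Rsad2, Cxcl10 and Ifit genes. The libraries differed in their mix of clusters, and this cluster made up 21.8%, 31.0%, 35.6% and 51.2% of the class. Interferon-induced genes define it, so its share is no separate measure of their change. Within 5 clusters, a check chosen after seeing the data, the type I median was 0.076 to 0.59, with 17 to 21 of 21 genes higher. Against the WT mean it was −0.036 to 0.29 in cKO replicate 1 and 0.17 to 0.84 in cKO replicate 2, while WT replicate 2 lay above WT replicate 1 by 0.10 to 0.26.

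ER stress genes in monocyte-like cells lay higher in 20 of 22 (median 0.16, adjusted p = 0.000322, and adjusted p = 0.824 with an estimated correlation), with Creld2 at 0.49 ± 0.14 and the stress transcription factor gene Ddit3 at 0.34 ± 0.11. The adjusted p was 0.143 without cKO replicate 2. The inflammatory macrophage list was higher in 10 of 17 (median 0.17, adjusted p = 0.00705, and adjusted p = 0.824 with an estimated correlation), with Nos2, the inducible nitric oxide synthase, at 1.21 ± 0.23. Its adjusted p was 0.0869, downward, without WT replicate 2. The erythroid and platelet markers lay lower (4 of 6 lower, median −2.05, adjusted p = 0.00301, 4 genes passing when adjusted over the list alone, and adjusted p = 0.824 with an estimated correlation), with Hba-a1 at 1.08, 3.59, 0.538 and 0.623 CPM. Their adjusted p was 0.375 without WT replicate 2 and 0.419 without cKO replicate 1. T cell receptor activation genes lay higher in this class (12 of 18, median 0.35, adjusted p = 8.69e-05, and adjusted p = 0.824 with an estimated correlation), with Il2ra at 1.25 ± 0.23. Their adjusted p was 0.189 without WT replicate 2. Cytotoxic effectors did too (13 of 18, median 0.31, adjusted p = 0.0118, and adjusted p = 0.824 with an estimated correlation). Without WT replicate 2 and cKO replicate 2 their adjusted p was 0.833 and 0.31. The 56 carried-over transcripts were at 2.13, 1.34, 2.01 and 3.00 UMIs per 10000 in monocyte-like cells. There cKO replicate 1 lay between the WT libraries. Of 11441 genes edgeR called 0, 647 had an unadjusted p under 0.05 (572 expected by chance), and DESeq2 called 21 (19 higher, 2 lower). The groups did not overlap in 33.3%, the share chance gives. Without WT replicate 1 or WT replicate 2 edgeR called 1 gene, and without cKO replicates 1 and 2 it called 28 and 3.

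**Figure D4:**
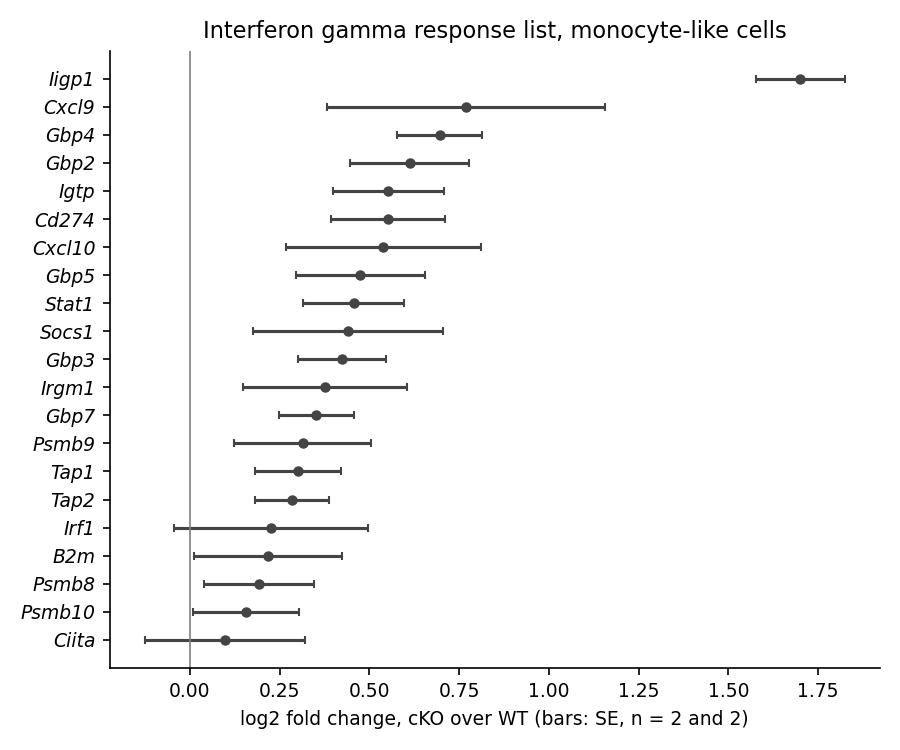
Log2 fold change, cKO over WT, of the interferon gamma response genes in monocyte-like cells, with a point per gene and bars for standard errors. The list medians of single libraries against the WT mean, which are not drawn, are −0.15 and 0.15 in the WT and 0.31 and 0.43 in the cKO libraries.

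Among dendritic cells, migratory DC-like cells held 2 genes that passed. Ly6i was at 10.8, 4.49, 89.4 and 88.8 CPM (3.42 ± 0.42, adjusted p = 0.0175) and so rose in the cKO libraries, and Areg, which encodes the growth factor amphiregulin, was at 151, 243, 21.9 and 13.9 CPM and fell by 3.43 ± 0.37 on the log2 scale (adjusted p = 0.0112). Both stayed past the threshold with each library left out. In pDC-like cells, the main producers of type I interferon, Hspa1a (766, 777, 1483 and 2137 CPM; 1.23 ± 0.18), Hspa1b (1051 and 903 CPM in the WT and up to 2660.0 CPM in the cKO libraries; 1.25 ± 0.18) and the stress transcription factor gene Atf3 (97.0, 111, 227 and 334 CPM; 1.44 ± 0.21) rose, each with an adjusted p of 0.0485, though Atf3 is more than 10 times higher in another class. Without cKO replicate 2 the adjusted p was 0.101 for Hspa1a in pDC-like cells, 0.0793 for Hspa1b in pDC-like cells and 0.0875 for Atf3 in pDC-like cells. The heat shock list in pDC-like cells lay higher in 18 of 20 (median 0.46, adjusted p = 3.94e-16, and adjusted p = 0.824 with an estimated correlation), with 7 genes passing when adjusted over the list alone and 3 over all genes. This call held with each library left out.

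In cDC2-like cells, antigen-presenting cells that favour CD4 T cells, all 22 ER stress genes were higher (median 0.22, adjusted p = 2.23e-05) and 19 of 21 interferon gamma genes (median 0.20, adjusted p = 9.8e-08), with the PD-L1 gene Cd274 at 0.45 ± 0.11 and Iigp1 at 0.90 ± 0.19. Both calls held with each library left out, and with an estimated correlation the adjusted p of both was 0.824. Lymphocyte transcripts were higher in cDC2-like cells of the same libraries. The 56 carried-over transcripts were at 3.81, 3.68, 4.69 and 5.74 UMIs per 10000. T cell receptor activation genes lay higher in 13 of 18 (median 0.25, adjusted p = 0.000454, and adjusted p = 0.824 with an estimated correlation). Their adjusted p was 0.209 without cKO replicate 2. The apoptosis and p53 list was higher in 11 of 14 (median 0.19, adjusted p = 0.00171, and adjusted p = 0.824 with an estimated correlation), with Mdm2, the negative regulator of p53, at 0.48 ± 0.11. Its adjusted p was 0.0619 without cKO replicate 1. MHC class II genes were lower in 10 of 11 (median −0.17, adjusted p = 0.0141, and adjusted p = 0.824 with an estimated correlation), although the class II transactivator gene Ciita was at 0.25 ± 0.098. That call ended without WT replicate 1 (0.06), WT replicate 2 (0.0662) or cKO replicate 2 (0.122). In cDC1-like cells the myeloid markers were higher (9 of 11, median 1.07, adjusted p = 1.93e-16, and adjusted p = 0.824 with an estimated correlation), with Apoe at 26.9, 100.4, 293 and 238 CPM, and type I interferon genes too (18 of 19, median 0.31, adjusted p = 1.87e-07, and adjusted p = 0.824 with an estimated correlation), though that adjusted p was 0.0612 without cKO replicate 2. In B-like cells the type I interferon list was not called (9 of 20 higher, median −0.15). Of the genes tested, edgeR called 0 in cDC1-like, cDC2-like and B-like cells, and DESeq2 called 0, 1 and 2. An unadjusted p under 0.05 was found for 258, 421 and 197 genes, against 375, 522 and 341 expected by chance. Over the 5 dendritic and B-like classes and gamma-delta T-like cells, edgeR called 5 genes, and 59, 111, 320 and 139 without WT replicates 1 and 2 and cKO replicates 1 and 2.

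Over all classes, camera with the preset correlation called 79 of 243 pairs of list and class, 67 higher and 12 lower. With an estimated correlation it called 0, and fry called 0. Both rest on 2 residual degrees of freedom, so 0 calls do not show that the lists were unchanged.

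The difference of effects between T-like and macrophage-like cells was tested because the ablation is placed in T cells. The change between genotypes differed for 58 of 11997 genes, 1 with a higher and 57 with a lower log2 fold change in T-like than in macrophage-like cells. Of the 57, 56 had over 10 times the CPM in another class, among them T and NK cell genes such as Cd3e, a chain of the T cell receptor complex (difference −2.15 ± 0.23, adjusted p = 0.00184), Lat (−2.54 ± 0.28), Pdcd1 (−1.67 ± 0.26, adjusted p = 0.00983) and Ifng (−2.31 ± 0.35, adjusted p = 0.00865). The other was Ly6c2, a monocyte and T cell surface gene (−1.01 ± 0.15). In T-like cells themselves Cd3e was at −0.068 ± 0.14 and in macrophage-like cells at 2.05 ± 0.30. Ufl1 differed by −0.065 ± 0.28 (adjusted p = 1.00). Without WT replicates 1 and 2 the count was 130 and 28, and without cKO replicates 1 and 2 it was 91 and 30. Between CD8 T-like and Treg-like cells 2 of 8552 genes differed, the receptor segments Trbv15 (4.67 ± 0.36, adjusted p = 4.37e-05) and Trbv29 (−6.78 ± 0.76, adjusted p = 0.00189), and Il1r2 was at 4.21 ± 0.67 (adjusted p = 0.0699). That count was 17 without WT replicate 2, 6 without cKO replicate 1 and 12 without cKO replicate 2.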

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

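Of the tests in this part, the reading of free RNA from macrophage-like cells with no lymphocyte UMIs was chosen after the result was seen, as was the return of macrophage-like cells kept out for other RNA.

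The difference of effects between T-like and macrophage-like cells stood out because the test of the difference itself called 58 genes, nearly all T and NK cell transcripts that were higher in macrophage-like cells of the cKO libraries. Free RNA shared by all droplets would leave fewer macrophage-like cells without UMIs of these genes. Those made up 41.6% and 48.5% in the WT and 35.6% and 38.6% in the cKO libraries, a fall in that direction, so the question was its size. The mean that this share implies was at most 1.43 times as high in a cKO as in a WT library. For the mean UMIs per cell the ratio was 3.75. For these genes that gap argues against free RNA as the whole source. The genes were picked for their rise in these libraries, so 3.75 is no independent measure of that rise. A test on monocyte-like cells decided nothing by itself, since their UMIs per cell were 0.565 and 0.477 times those of macrophage-like cells in the cKO libraries, on both sides of the bound of 0.5. At least 72.7% of these UMIs in each cKO library (88.5% in cKO replicate 2) lay in macrophage-like cells that held 5 or more of them, 5.26% and 9.03% of the cells. In the WT libraries 38.9% and 48.3% lay in such cells. In cDC2-like cells the same share was high in the WT libraries too, at 75.2% and 68.3% against 80.3% and 85.0% in the cKO libraries. T or NK cells that shared a droplet with a macrophage or were counted in its clusters are a candidate source. Whether such pairs formed in the tumour, through contact or uptake, or during preparation was not tested.

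Between CD8 T-like and Treg-like cells, the test of the difference called 2 receptor segments, Trbv15 and Trbv29. Xist was found at 292 CPM in cKO replicate 2, in data outside the comparisons, and Eif2s3y, Ddx3y, Uty and Kdm5d had 4, 1, 2 and 0 UMIs there, a count of 0 that allows up to 3. An unnamed cluster of low-UMI barcodes, at a median of 601 UMIs, held 287 cells in cKO replicate 2 (3.83% of its cells) against 98, 18 and 0 in WT replicates 1 and 2 and cKO replicate 1.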

How the results depend on the processing

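Of 156 values of the 16 main results under alternatives, 72 were rated the same, 61 passed more genes, 7 were weaker and 16 changed sign. For counts of calls, the same means a number within a set factor, even where other genes or lists were called. For shares and ratios it means a move smaller than the SD within groups. Of 3945 values for 404 single genes, 3706 kept their direction and side of the threshold, 208 newly passed, 5 no longer passed and 26 changed sign. The alternatives for gene lists without a library, for the further classes, for the gate in single genes and for the returned macrophage-like and NK-like cells were chosen after seeing the data. The cause was not tested, except that without the expression filter genes with few counts enter the fit, and that leaving out a library leaves 1 in its group. In simulated data with 2 libraries per group, edgeR recovered from 89.4% to 100% of genes changed 4-fold and from 1.49% to 41.8% of those changed 1.5-fold. Replicate numbers are shared by WT and cKO libraries, but the labels do not say that they mark pairs. The deviations of libraries with the same number correlated at −0.0552 (cDC1-like) to 0.254 (monocyte-like cells), so that pairing is not established. The block counts below stand for a pairing that remains open.

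Genes called without the expression filter were 59 in all T-like, 63 in CD8, 18 in CD4, 31 in Treg-like, 44 in NK-like, 171 in macrophage-like and 266 in monocyte-like cells, and 333 in the other classes. The DESeq2 Wald test called 1 in CD8, 3 in CD4, 2 in NK-like, 29 in macrophage-like and 21 in monocyte-like cells, and 9 in the other classes. With the replicate number as a block there were 0 in CD4, 7 in Treg-like, 26 in NK-like, 43 in macrophage-like and 1 in monocyte-like cells, and 16 in the other classes. Doublets kept gave 5 in Treg-like, 2 in NK-like and 1 in monocyte-like cells, resolution 2 gave 4 in Treg-like cells, the UMI gates gave 2 in CD4 and 1 in Treg cells, and the returned cells gave 1 in macrophage-like and 0 in NK-like cells. Leaving out libraries gave from 0 to 70 in all T-like, 0 to 6 in CD8, 2 to 35 in CD4, 4 to 16 in Treg-like, 1 to 27 in NK-like, 0 to 132 in macrophage-like and 1 to 28 in monocyte-like cells, and 59 to 320 in the other classes.

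Of the gene lists, 0 were called with an estimated correlation, 0 with fry, 82 with the block (75 of them shared with the main call), 82 with the returned NK-like cells (79 shared) and 76 to 101 without a library. The difference between T-like and macrophage-like cells was called for 33 genes with DESeq2 size factors, 154 without the filter, 40 with the returned macrophage-like cells and 28 to 130 without a library. That between CD8 T-like and Treg-like cells was called for 28 without the filter and 3 to 17 without a library.

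Ufl1 in all T-like cells was at 0.00078 without the filter, 0.017 with doublets kept, 0.036 at resolution 2 and −0.30 to 0.22 without a library. Pdcd1 in CD8 T-like cells was at 0.12 with the block, 0.068 at resolution 2, 0.12 with the UMI gate and −0.56 to 0.86 without a library. The CD8 difference in share was −2.11 to 1.95 and that of all T-like cells −3.97 to 4.12. The log2 ratio of CD8 T-like to Treg-like cells differed by 0.086 between genotypes, by −0.0080 with doublets kept and by −0.78 to 0.95 without a library.

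Among single genes, Ufl1 in CD8 T-like cells was at 0.025 with DESeq2, 0.049 with doublets kept, 2.2e-05 at resolution 2 and −0.13 to 0.26 without a library. Without a library, Pdcd1 in all T-like cells was at −0.55 to 0.96, Pdcd1 in Treg-like cells at −0.14 to 0.71, Ufl1 in Treg-like cells at −0.091 to 0.85, Pdcd1 in gamma-delta T-like cells at −0.17 to 0.44 and Ufl1 in gamma-delta T-like cells at −0.12 to 0.88. Doublets kept gave −0.13 for Hp, 0.11 for Mpp7, −0.020 for Odr4 and −0.29 for Tigit in macrophage-like cells, and −0.0043 for H2-Ob in monocyte-like cells. Top2a in CD8 T-like cells was at −0.44 at resolution 2 and −0.17 with the UMI gate. In CD4 cells the gate gave −0.015 for Ufc1, 0.80 for Xcl1, 0.27 for Klrc1, 0.048 for Bach2 and 0.39 for Myc, and in Treg cells 0.014 for Uqcrh.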

Other observations

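In this part, both tests of the heat shock pattern and the test of the cluster mix as the whole cause were chosen after the result was seen. The test of the mix's part and that on cKO replicate 1 were set before.

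Receptor beta V segments differed between the tumours' CD8 T-like cells. The leading segment was Trbv17 with 23.4% of Trbv UMIs in WT replicate 1, Trbv20 with 36.2% in WT replicate 2, Trbv16 with 25.2% in cKO replicate 1 and Trbv15 with 24.8% in cKO replicate 2. The effective number of segments (inverse Simpson) ranged from 5.41 in WT replicate 2 to 9.06 in cKO replicate 1. In Treg-like cells Trbv1 led in WT replicate 2, cKO replicate 1 and cKO replicate 2, with 35.7%, 20.9% and 40.2%, and Trbv15 in WT replicate 1 with 18.3%. In conventional CD4 T-like cells no segment exceeded 16.6%, and the effective number was 11.3, 12.5, 11.9 and 12.8. UMIs of expanded clones weigh by cell number and expression, and no clonotypes were called.

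Hspa1a and Hspa1b, inducible chaperone genes, were higher in the cKO libraries in many classes. Both cKO libraries lay above both WT libraries for both genes in 8 of 12 classes, which leaves a shift of whole libraries, through handling or the tumour, undecided between the bounds set for it. An effect limited to T cells is argued against only weakly. The mean log2 fold change was 0.59 over 8 classes other than T cells, with an SD of 0.39, against 0.64 over 4 T-like classes. However, the classes come from the same libraries, so the SD over them is no spread between libraries. The 2 genes passed the threshold in pDC-like cells only. The groups overlapped for both genes in monocyte-like, cDC2-like and macrophage-like cells and for Hspa1a in conventional CD4 T-like cells. In macrophage-like cells the log2 fold changes were 0.039 ± 0.23 for Hspa1a and −0.0033 ± 0.22 for Hspa1b. The digestion, freezing and thawing that the labels describe may induce these genes, and the genotype of the host remains an open alternative.

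Interferon gamma response genes were higher in monocyte-like cells of the cKO libraries, by a list median of 0.43 in log2 CPM (0.42 in edgeR), and Ifng was at 0.51 ± 0.13 in all T-like and 0.68 ± 0.12 in NK-like cells without passing. Another mix of monocyte-like clusters as the whole cause is argued against only weakly. Within 5 clusters the list median was 0.13 to 0.43, with 17 to 21 of 21 genes higher. Its mean of 0.27 lay above 0 by more than the SD over clusters (0.13) and that of the WT libraries within clusters (0.09). However, the clusters come from the same libraries, so the SD over them is no spread between libraries. Within single clusters WT replicate 2 lay above WT replicate 1 by −0.033 to 0.27, in some as far as the change itself. The mix could still account for part, and how large a part stays open, since 0.27 does not exceed 0.5 times the 0.43 of the whole class by more than the SD of 0.13. A property of cKO replicate 2 alone, such as its sex or depth, cannot be told apart from a change in both cKO libraries, since the list median in cKO replicate 1 was 0.31 against the WT mean, with a spread of 0.22 between the WT libraries. Whether interferon gamma from lymphocytes acts on the monocytes was not tested.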
